A study of Mus musculus with 2 samples.

How the data were processed

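The study sequenced RNA from forelimb cells of mouse embryos of mixed strain background at embryonic day 13.5. Per the labels and the series' design text, 6 forelimbs (3 pairs) were pooled for each sample, cells were separated by fluorescence-activated sorting into ScxGFP-positive and ScxGFP-negative cells and frozen, total RNA was extracted with the RNeasy micro kit, and cDNA was made with the NuGEN Ovation RNA-Seq v2 assay. That chemistry amplifies very small amounts of RNA and does not mark strand, so reads of a gene and of an overlapping antisense gene are not told apart. There were 2 samples in 2 groups, with 1 library each, and the groups were taken from the labels' cell population.

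Per the submitters' processing notes, Bowtie 0.12.7 and TopHat 1.4.1 were used with the mouse build mm9; the version of the program that estimated abundance is not given in the sources used here. Per the file headers, each deposited file lists RefSeq transcripts with a gene symbol, a position, a length, a coverage, an FPKM and a status, the layout of Cufflinks output. The authors' deposited FPKM is the estimated number of fragments of each transcript, normalised to its length in kilobases and to the number of mapped fragments. The coverage, also as deposited per the file headers, is the estimated depth of aligned bases over the transcript, and the length is the deposited transcript length in bases. Each file held 28107 transcript rows under 22096 symbols. Status was OK in 27808 rows of the positive library and 27807 of the negative library, LOWDATA in 294 of each and FAIL in 5 and 6. Rows at exactly 0 numbered 5997 and 5649. Symbols with a failed row were treated as missing: *Kdelr3* and *Ddx17* in the positive library and *Hba-a1*, *Hba-a2*, *Cnot1* and *4930513N10Rik* in the negative library, all 6 listed at 0 there. An exact 0 can thus be a failed estimate, and a gene at 0 is described only as listed at 0.

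In 3284 rows the length equalled end minus start and in 0 rows end minus start plus 1, so positions in the files count from 0 and 1 was added to each start; positions are of mm9. The reference annotation at hand is of another build, and its positions were not used.

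FPKM was summed over the rows of a symbol. A gene counted as measured with an FPKM of at least 1 in at least one library, which left 12096 genes. The measure of difference was log2((FPKM positive + 1) / (FPKM negative + 1)), with a pseudocount of 1. With 1 library per group there is no test and no p-value, and genes were described by size, at least 2-fold in either direction. The share of higher genes has an exact Clopper-Pearson 95% interval, which covers the counting of genes only. For each gene list the median log2 ratio of its measured members was compared with 10000 random lists of the same size, drawn from measured genes matched on mean log2(FPKM + 1) in 20 bins. A list was said to stand apart below percentile 2.5 or above 97.5, as a description of these libraries. Lists matched on length as well used 10 level bins with 5 length bins in each.

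Chosen before the data were examined were the 20 gene lists, the threshold, the filter, the pseudocount, the scaling alternatives and the rule for named genes. That rule took *Scx* first, then the 12 highest and 12 lowest ratios among 5676 genes with an FPKM of at least 5 in one library and status OK in both, without small RNAs known by symbol and without Rik and Gm symbols, of which 0 would have ranked among them. It also took up to 4 members of each list with the largest absolute ratio, with the largest of opposite sign where the 4 share a sign, 15 genes whatever their value, and the 5 highest and 5 lowest of 74 symbols of transcription factor families. It named 109 genes, of which the text gives most; 1 of them is not reported here. *AF357355* is a small RNA whose symbol does not show it. No gene is in more than 1 of the 20 lists. Of listed genes, *Col6a3* and *Ahsp* were not analysed here, and *Hba-a1* and *Hba-a2* were missing for the reason above. A further 4 lists (mast cell and basophil, neutrophil, imprinted, and axon guidance genes) were written after the values had been seen, as was a second list of 42 muscle genes used in 1 test; they are described only in the closing section.

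The depth behind a value was followed through coverage. Coverage divided by FPKM was constant within a library, 2.28 and 2.39, which corresponds to 2.28 and 2.39 gigabases of mapped sequence if FPKM was scaled by all mapped fragments. Summed over transcripts, coverage times length gave 0.687 gigabases in the positive and 0.875 in the negative library, 30.1% and 36.6% of those totals. Read counts could not be recovered as whole numbers from the FPKM, so no count test was run. Aligned bases, coverage times length, are printed for some of the named values that rest on little sequence. The FPKM sum was 161924 in the positive and 220509 in the negative library. Of these, the mitochondrial ribosomal RNA-like gene *Mtrnr2l* took 11.0% and 12.3%, small RNAs 19.8% and 14.7% and haemoglobin genes 0.139% and 5.52%. A scaling without haemoglobin genes had been set beforehand, and that without small RNAs was added after the data were seen. No scaling left out *Mtrnr2l*. *AF357355* and *Snord19*, both 54 bases, were listed at 2646 and 5291 FPKM in the positive library, in a ratio of exactly 2; FPKM of such short transcripts is unstable.

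The alternatives were pseudocounts of 0.1 and 5, no filter or a minimum FPKM of 5, the median ratio set to 1, equal upper quartiles, FPKM rescaled to the same sum in each library (TPM, with and without haemoglobin genes), only rows with status OK, the highest row per symbol in place of the sum, and thresholds of 1.5-fold and 4-fold. Added after seeing the data were removal of the median trend over 20 bins of transcript length, TPM without small RNAs, failed estimates kept at 0, the tendon list without *Scx*, and random lists matched on length too. A comparison of estimation intervals on each FPKM was intended and not run, since the columns hold none.

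The steps were tested on simulated data made from the 12096 measured genes, with 200 genes changed by known folds in the comparison of positive with negative cells. The changed genes were drawn only from those with a geometric mean FPKM over the libraries of at least 5. The simulated noise was of one size at every level. The shares recovered therefore do not cover genes at lower levels. The noise size, a log2 standard deviation of 0.43, was taken from the spread of the observed ratios, since there were no replicates. The share of unchanged genes that passed follows from that choice and is no measured error rate. Of genes changed 8-fold, 100% passed the 2-fold threshold in both directions. Of genes changed 4-fold, 94% passed when raised and 100% when lowered, and 1.01% of unchanged genes passed. Of simulated lists of 15 unchanged genes 5% stood apart, a share that the percentile limits set in advance, and of lists moved by 1 on the log2 scale 100% did. The work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.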

Results

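Transcript abundance was measured by RNA sequencing in cells of mouse embryonic forelimbs at E13.5 of gestation, sorted by flow cytometry on a green fluorescent reporter. In ScxGFP embryos the reporter is driven by regulatory sequence of *Scx*, which encodes scleraxis, a transcription factor of tendon and ligament progenitors. The comparison asks how gene expression in ScxGFP-positive cells differs from that in ScxGFP-negative cells of forelimbs of this stage. Each population gave 1 library, made from cells of 6 pooled forelimbs (3 pairs). There were therefore no replicates and no test: each difference below describes these 2 libraries and has no replicate check. Values are the deposited FPKM (fragments normalised to transcript length and to the number of mapped fragments), summed over the transcripts of a gene, and folds and log2 ratios are on the FPKM + 1 scale, which understates the change of genes at low levels. In the positive library 10752 genes had an FPKM of at least 1, and in the negative library 11497 did. The constant ratio of deposited coverage to FPKM, 2.28 and 2.39, corresponds to that many gigabases of mapped sequence under the usual scaling of FPKM, so total mapped sequence was similar. Sequence on the listed transcripts was less alike, at 0.687 gigabases in the positive and 0.875 in the negative library, 30.1% and 36.6% of those totals.

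*Scx* itself, the gene behind the sort, was the check of the labels. Its FPKM was 134 in the positive library and 1.69 in the negative library, a log2 ratio of 5.65 (NM_198885, mm9 chromosome 15, 76287868 to 76289898). Of 12096 genes with an FPKM of at least 1 in either library, 488 were at least 2-fold higher in ScxGFP-positive cells, 1207 were at least 2-fold lower and 10401 were neither. At 4-fold the counts were 166 higher and 354 lower, and at 8-fold 89 and 142. The median log2 ratio of all measured genes was −0.27, a 1.20-fold shift toward the negative library, and list medians below are also given relative to it where they lie close to it. The higher genes made up 28.8% of those past 2-fold (exact binomial 95% interval 26.6 to 31.0, which covers the counting of genes only). That split depended on the scaling: with the median ratio set to 1 it was 683 higher and 957 lower (41.6%), with equal upper quartiles 684 and 957 (41.7%), and with FPKM rescaled to equal sums (TPM) 1593 and 1611 (49.7%). TPM without haemoglobin genes gave 1468 and 1712 (46.2%), and without small RNAs 1732 and 1536 (53.0%), so the larger side changed there. The median of all genes was −0.018 and −0.017 under the first and second of these scalings and 0.12, 0.044 and 0.20 under the rest.

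**Figure D1:**
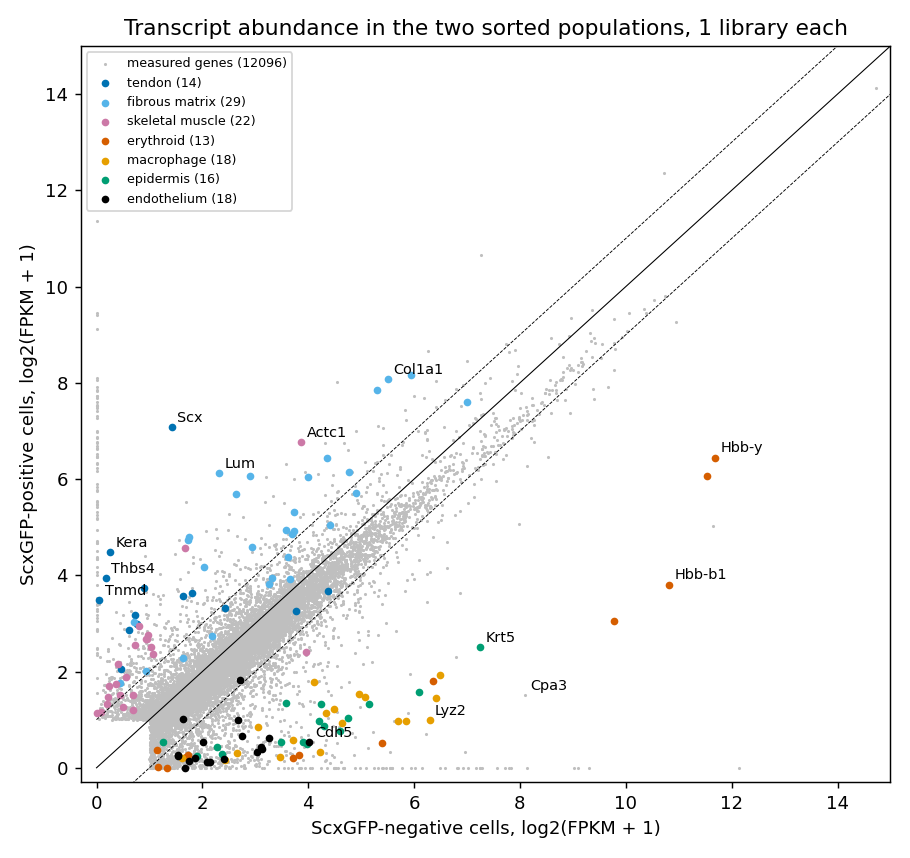
Abundance of 12096 measured genes in the 2 libraries, as log2(FPKM + 1), with ScxGFP-negative cells on the x axis and ScxGFP-positive cells on the y axis; each point is a gene, the solid line marks equality and the dashed lines 2-fold. Tendon, fibrous matrix and skeletal muscle genes lie mostly above the line, *Scx* at 134 against 1.69 FPKM, and erythroid, macrophage, epidermal and endothelial genes lie below it, *Hbb-y* at 85.8 against 3303 FPKM.

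Genes of the tendon lineage were higher in ScxGFP-positive cells. *Kera*, which encodes the corneal and tendon proteoglycan keratocan, stood at 21.4 FPKM against 0.192, the matrix protein gene *Thbs4* at 14.4 against 0.128, and *Tnmd*, encoding the tendon membrane protein tenomodulin, at 10.2 against 0.0361. The negative value of *Tnmd* rests on about 114 aligned bases and that of *Kera* on about 895, so their folds are poorly bounded. Of 14 measured tendon genes, 11 were at least 2-fold higher and 0 were lower by as much; their median log2 ratio was 2.24, at percentile 100 among 10000 random lists of the same size matched on level, and 2.22 with *Scx* left out. It was 3.24 with a pseudocount of 0.1 and 1.14 with a pseudocount of 5, at percentile 100 in both. The proteoglycan gene *Fmod* had a ratio of 1.82 (11.4 against 2.51 FPKM). *Mkx*, a tendon transcription factor, was higher in positive cells but below 2-fold on the FPKM + 1 scale, at 0.89 (8.97 against 4.36 FPKM). Its FPKM in positive cells was 206% of that in negative cells, and its log2 ratio lay 1.16 above the median of all genes. *Tnc*, which encodes tenascin C, lay on the other side, at 11.7 FPKM in positive cells and 19.9 in negative cells. *Kera* (NM_008438, mm9 chromosome 10, 97069839 to 97076322) lies beside *Lum* (97028135 to 97035337) and *Dcn* (96942134 to 96980796), which were among the 12 highest ratios too.

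Collagens and other components of fibrous matrix were higher as a group. *Col1a1*, the main chain of type I collagen, stood at 268 FPKM in ScxGFP-positive cells and 44.6 in negative cells (mm9 chromosome 11, 94797584 to 94813170). The leucine-rich proteoglycan genes *Lum* and *Dcn* stood at 68.4 against 3.97 and at 66.2 against 6.42 FPKM, and the type VI collagen genes *Col6a1* and *Col6a2* at 26.8 against 2.37 and 50.8 against 5.18. Of 29 measured genes in this list, 20 were at least 2-fold higher, 9 were within 2-fold and 0 were lower by that much, with a median log2 ratio of 1.39 at percentile 100. None of these 29 genes is in the tendon list.

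Other genes with the largest ratios were not in a matrix or tendon list. *Agtr2*, encoding the type 2 angiotensin receptor, stood at 45.2 FPKM in positive cells and 2.21 in negative cells (NM_007429, mm9 chromosome X, 21061752 to 21065957). *Egfl6*, encoding a secreted EGF-repeat protein, stood at 25.4 against 1.95 (chromosome X, 162960939 to 163023648), and *Dlk1*, an imprinted gene for a Notch-ligand-like membrane protein, at 20.3 against 0.884 (chromosome 12, 110691665 to 110701546). The highest ratio among genes eligible for naming belonged to *AF357355*, a 54-base RNA listed at 2646 FPKM in positive cells and at 0 in negative cells. FPKM of so short a transcript is unstable: of 640 transcripts shorter than 100 bases, 146 were above 0 in the positive and 134 in the negative library, and no fold is given for it.

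In the list of muscle connective tissue and loose fibroblast genes, some transcription factor genes were higher in ScxGFP-positive cells and others were within 2-fold. The transcription factor gene *Ebf2* stood at 9.61 FPKM against 0.029 (about 301 aligned bases), *Osr2* at 8.56 against 0.570 and *Meox2* at 30.0 against 3.80. The matrix gene *Dpt* (dermatopontin) stood at 8.10 against 0.974. Of 10 measured genes 6 were at least 2-fold higher and 1 was lower, the collagen gene *Col15a1* at 0.822 against 5.36 FPKM; the median log2 ratio was 1.71, at percentile 100. Without the filter on low values it was 0.55, at percentile 100; the genes this adds, *Dpp4*, *Pi16* and *Ly6a*, named here after their values were seen, lay under 1 FPKM in both libraries, at 20.7%, 30.8% and 60.7% of the negative value. Pericyte and smooth muscle genes had 6 measured members, of which 2 passed 2-fold, *Acta2* (smooth muscle actin) at 19.9 against 2.54 FPKM and *Abcc9* at 1.81 against 0.381. Their median was 0.65 at percentile 99.9. The rest of the 12 listed genes (*Rgs5*, *Myh11*, *Cnn1*, *Tagln*, *Foxs1* and *Higd1b*) lay under 1 FPKM in both libraries, so the median covers only part of the list.

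Skeletal muscle genes were higher in the ScxGFP-positive library. *Actc1*, the cardiac actin that embryonic skeletal muscle also expresses, stood at 107 FPKM against 13.6, the slow troponin gene *Tnnt1* at 22.8 against 2.18, *Tmem8c*, which encodes the fusion protein myomaker, at 6.71 against 0.737, and *Myod1*, the myogenic regulator, at 4.84 against 0.663. Of 22 measured muscle genes 18 were at least 2-fold higher, with a median log2 ratio of 1.35 at percentile 100. The 1 gene lower by as much was *Mef2c*, at 4.30 against 14.5 FPKM, a transcription factor gene also expressed in endothelium and other tissues. With a pseudocount of 5 the median was 0.49, since most members lie at low FPKM, and with TPM it was 2.49.

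Cartilage genes did not move together. *Col2a1*, the main cartilage collagen, stood at 68.1 FPKM in positive cells and 40.4 in negative cells, a log2 ratio of 0.74. *Lect1*, which encodes chondromodulin (6.41 against 0.435), and *Col11a1* (19.01 against 5.36) were more than 2-fold higher, whereas *Papss2* (6.32 against 21.1) and *Chst11* (1.56 against 4.85), both enzymes of glycosaminoglycan sulphation, were more than 2-fold lower. *Sox9*, the chondrocyte regulator, had a ratio of −0.41 (13.9 against 18.9 FPKM) that was 0.0069 with TPM. Of 18 measured genes 3 were higher, 3 lower and 12 neither; the median was −0.15, or 0.12 above that of all genes, at percentile 85.7. Its sign turned with the scaling, from −0.15 to 0.081 with the median ratio set to 1, and without the filter on low values it was 0.034 at percentile 99.3.

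Among genes of the joint interzone, the tissue between future skeletal elements, *Sfrp2*, a secreted Wnt antagonist (44.9 against 8.02 FPKM), and *Enpp2*, the gene for autotaxin (12.2 against 1.88), were higher in positive cells. *Cd44* (2.85 against 9.28) and *Wnt4* (1.96 against 5.50) were lower, and *Gdf5*, a growth factor of developing joints, was at 2.44 against 3.23, below 2-fold. Of 14 measured genes 3 were higher, 2 lower and 9 neither, with a median of 0.10, or 0.36 above that of all genes, at percentile 99.4. After removal of the trend with transcript length, the median was −0.028, at percentile 97.0. Genes of osteoblasts and perichondrium went both ways. *Runx2*, the osteoblast regulator, stood at 4.16 FPKM against 12.2, and the homeobox genes *Dlx5*, *Dlx3* and *Dlx6* at 4.71 against 33.5, 0.309 against 4.94 and 0.573 against 3.41. Of 10 measured genes 5 were at least 2-fold lower, 4 were within 2-fold and 1 was higher, *Bmp3* at 3.86 against 1.12; the median was −0.90 at percentile 0.09. *Dlx3*, *Dlx5* and *Dlx6* are expressed in ectoderm as well, and without the filter on low values the median was −0.29 at percentile 7.83.

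Regulators of limb bud mesenchyme and patterning split in both directions. The homeobox genes *Msx2* (2.003 against 19.8 FPKM) and *Lhx9* (6.13 against 34.1), genes of distal mesenchyme, were lower in positive cells. *Twist2* (15.8 against 2.30) and the BMP antagonist gene *Grem1* (5.50 against 0.230) were higher. Of 25 measured genes 7 were at least 2-fold higher, 8 lower and 10 neither; the median log2 ratio of 0.039 lay 0.31 above that of all genes, at percentile 99.8. Among transcription factor families taken by symbol, the highest ratios included those of *Ebf2*, *Ebf3* (29.2 against 3.21 FPKM), *Six2* (12.3 against 0.870) and *Osr2*. *Ebf3* (mm9 chromosome 7, 144385354 to 144506128) and *Six2* (chromosome 17, 86083608 to 86087594) had log2 ratios of 2.84 and 2.83. Among the 5 lowest were *Gata2*, a haematopoietic and endothelial factor (0.687 against 36.2), *Msx2* and *Sox18*, an endothelial factor (0.539 against 8.59). The myosin genes *Myo1g* (0.0655 against 7.38, the former on about 495 aligned bases) and *Myo1f* (0.167 against 6.67) also met the symbol pattern but encode no transcription factor.

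**Figure D2:**
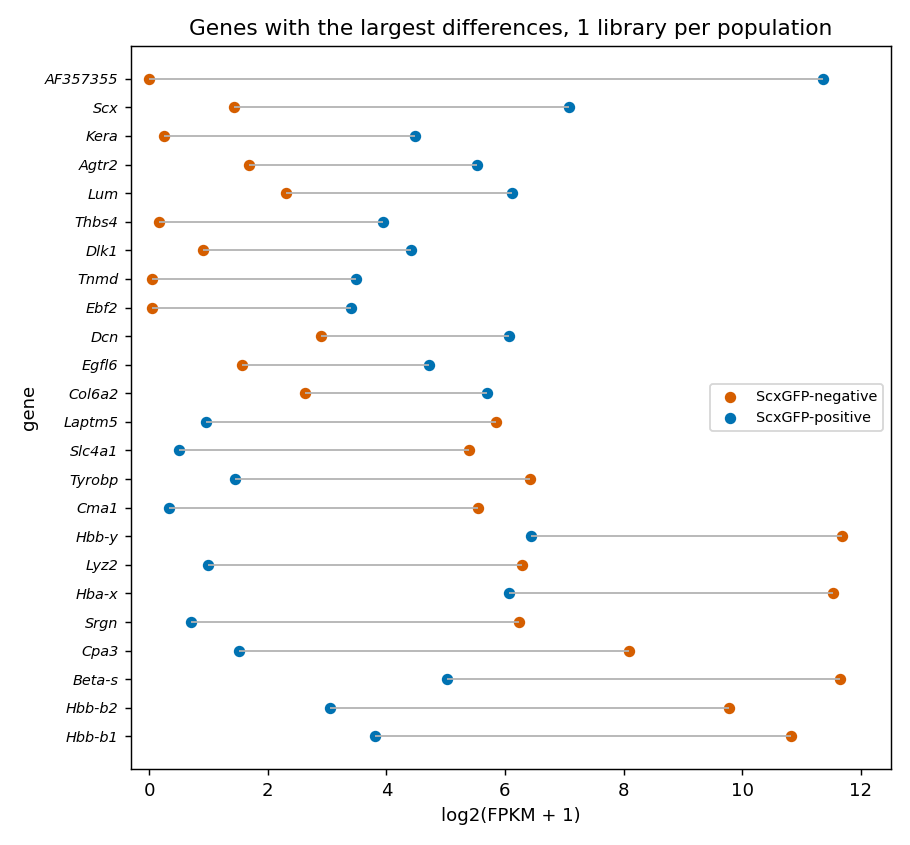
The 12 highest and 12 lowest log2 ratios among genes named by the rule, with log2(FPKM + 1) on the x axis and a gene in each row; blue points are the ScxGFP-positive library and orange points the ScxGFP-negative library, joined by a line. *Scx* spans 1.69 to 134 FPKM and *Hbb-b1* 13.0 to 1806 FPKM in the opposite direction.

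Blood cell genes were lower in ScxGFP-positive cells by the widest margins. The embryonic globin gene *Hbb-y* stood at 85.8 FPKM against 3303 (mm9 chromosome 7, 111000268 to 111001721) and *Hba-x* at 66.4 against 2974, and the erythrocyte anion exchanger gene *Slc4a1* at 0.424 against 41.0. *Hbb-b1* stood at 13.0 against 1806, *Hbb-b2* at 7.27 against 880 and *Beta-s* at 31.5 against 3197; these are near-identical copies, the first and second annotated at overlapping positions, so how reads were divided among them is uncertain. Of 13 measured erythroid genes 12 were at least 2-fold lower and 0 higher, with a median log2 ratio of −3.55 at percentile 0. Haemoglobin transcripts made up 0.139% of summed FPKM in the positive and 5.52% in the negative library, the latter a low estimate because *Hba-a1* and *Hba-a2* failed there and are listed at 0. All 18 macrophage and leukocyte genes were at least 2-fold lower, with a median of −3.35 at percentile 0. *Lyz2*, encoding lysozyme, stood at 0.979 against 77.4 FPKM, *Tyrobp* at 1.73 against 84.6, *Laptm5* at 0.950 against 56.5, *Coro1a* at 0.969 against 50.8 and *Ptprc*, which encodes the leukocyte antigen CD45, at 0.125 against 4.40. The granule protein genes *Cpa3*, *Cma1* and *Srgn* were also among the 12 lowest, at 1.85 against 271, 0.261 against 45.8 and 0.632 against 74.1; the value of *Cma1* in positive cells rests on about 641 aligned bases.

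Epidermal, endothelial and glial genes were lower in ScxGFP-positive cells as well. The basal keratin genes *Krt5*, *Krt14* and *Krt15* stood at 4.67 against 151, 1.504 against 34.3 and 0.688 against 23.2 FPKM, and *Perp*, a desmosome gene, at 1.98 against 67.1. Of 16 measured epidermal genes 15 were at least 2-fold lower and 0 higher (median −3.29, percentile 0). The endothelial cadherin gene *Cdh5* stood at 0.447 against 15.3, *Pecam1* at 0.250 against 7.15, *Emcn* at 0.307 against 7.75 and *Egfl7* at 0.349 against 7.57. Of 18 endothelial genes 16 were lower and 0 higher, with a median of −1.83 at percentile 0 that was −0.71 with a pseudocount of 5 and −3.70 with 0.1. Of 13 genes of Schwann cells and nerve 8 were lower and 0 higher, with a median of −1.36 at percentile 0. The glial transcription factor genes *Sox10* and *Foxd3* stood at 0.788 against 7.36 and 0.0644 against 4.17, the glial lipid-binding gene *Fabp7* at 0.796 against 13.6 and the axonal adhesion gene *L1cam* at 0.541 against 3.70. Some of the values in positive cells rest on little sequence: that of *Foxd3* on about 349 aligned bases, that of *Egfl7* on about 927. With a minimum FPKM of 5, the glial list kept its median of −1.36 but lay at percentile 6.62.

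**Figure D3:**
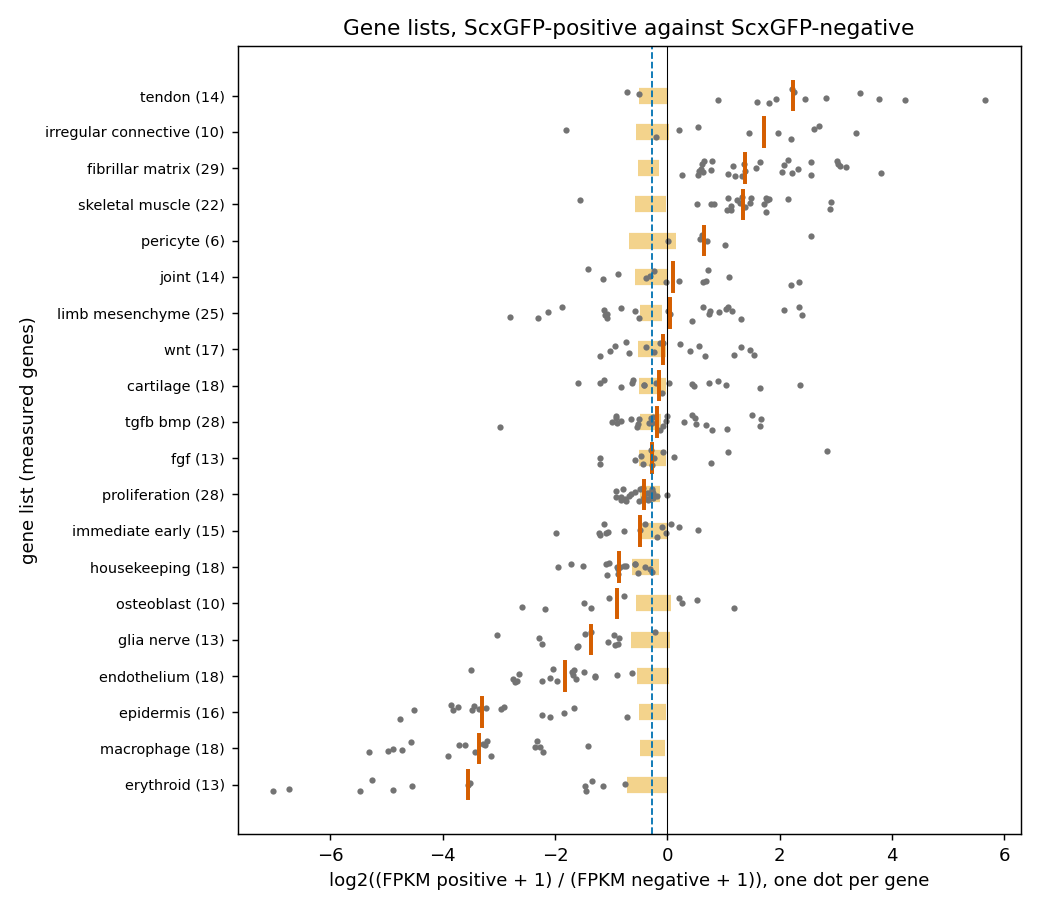
Log2 ratios of the measured members of 20 gene lists, in which each grey point is a gene, the orange bar the list's median, the yellow band the middle 95% of medians of 10000 random lists matched on level, and the dashed line the median of all genes, −0.27. Tendon (median 2.24) is at the top and erythroid (median −3.55) at the bottom; the signs of the cartilage, Wnt, TGF-beta and BMP, and FGF medians turned when the libraries were rescaled, that of the cell cycle median only when small RNAs were left out, and that of the joint median when the length trend was removed.

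Ligands and regulators of signalling pathways differed one by one more than as lists. *Fgf18* stood at 15.4 FPKM in positive cells against 1.29, a log2 ratio of 2.84, and the FGF feedback gene *Spry2* at 8.46 against 3.48, while the receptor gene *Fgfr2* (9.999 against 24.3) and the ERK phosphatase gene *Dusp6* (3.21 against 8.71) were lower. In the TGF-beta and BMP list, *Tgfb3* (9.68 against 2.74), *Ltbp1*, encoding a latent TGF-beta binding protein (26.2 against 7.67), and *Fst*, the follistatin gene (5.08 against 0.924), were higher, whereas *Tgfb1* was lower (0.370 against 9.81). The positive value of *Tgfb1* was 3.77% of its negative value. The median share was 3.92% among macrophage genes and 4.19% among epidermal genes, so this share does not single out a lineage. Which cells of the pools carry the differences in signalling genes was not tested. The secreted Wnt regulators *Dkk2* (21.3 against 6.67) and *Rspo3* (4.204 against 0.883) and the ligand gene *Wnt11* (2.35 against 0.344) were higher and *Tcf7*, a Wnt-responsive factor, was lower (1.90 against 5.63). In the FGF list 2 of 13 measured genes were higher and 2 lower, in the TGF-beta and BMP list 4 and 1 of 28, and in the Wnt list 4 and 2 of 17. Their medians of −0.27, −0.19 and −0.081 lay −0.0077, 0.077 and 0.19 from that of all genes, at percentiles 46.9, 87.3 and 93.3. With the median ratio set to 1 they were 0.010, 0.069 and 0.20, so their sign depended on the scaling. With TPM the Wnt list reached 1.03 at percentile 100.

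Cell cycle genes showed no member past 2-fold. *Mki67*, a marker of cycling cells, stood at 31.8 FPKM in positive and 45.01 in negative cells, *Pcna* at 36.4 against 69.6, *Ube2c* at 74.4 against 141 and the replication licensing genes *Mcm7* and *Mcm3* at 10.7 against 19.7 and 13.1 against 23.9. The median of 28 genes was −0.42, or −0.15 relative to all genes, at percentile 10.8; it was −0.027 with TPM and 0.060 when small RNAs were left out as well. Of 15 immediate early genes, which cell dissociation can induce, 6 were at least 2-fold lower in positive cells and 0 higher, with a median of −0.49 at percentile 3.13. Among them *Zfp36* stood at 3.36 against 16.1 FPKM, *Dusp1* at 3.80 against 10.1, *Fos* at 1.78 against 5.41 and *Ier2* at 2.52 against 6.65, and *Cyr61*, on the other side, at 8.30 against 5.36. This list passed below percentile 2.5 in 5 of the other 13 settings, such as TPM (−0.59, percentile 0.01). Commonly used reference genes were lower too: 6 of 18 by at least 2-fold and 0 higher, with a median of −0.86, or −0.59 relative to all genes, at percentile 0.02. *B2m* stood at 24.8 against 98.0 FPKM, *Hprt* at 5.08 against 18.9, *Gusb* at 3.21 against 10.96 and *Actb* at 416 against 888. Ratios also followed transcript length across genes, with medians of −0.60 in the shortest eighth of 4245 genes and −0.12 in the longest (Spearman's rho 0.38 across genes, which are not independent replicates).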

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

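Removal of the length trend, TPM without small RNAs, failed estimates kept at 0 and leaving out *Scx* were chosen after seeing the data; the other alternatives were set beforehand. No paired analysis was possible because each group has 1 library. The alternative based on intervals for each FPKM was not run, since the columns hold none. Over 13 alternatives, 13 of the 20 lists stayed above, below or within the range of matched random lists throughout, as in the report, among them tendon (medians 1.14 to 3.30, over 14 alternatives, the one without *Scx* included), fibrous matrix (1.12 to 2.11), skeletal muscle (0.49 to 2.63), muscle connective tissue (0.55 to 2.01), erythroid (−5.26 to −1.80), macrophage (−4.35 to −2.09), epidermis (−4.30 to −1.84) and endothelium (−3.70 to −0.71). Of list medians 216 stayed within the bootstrap 95% range over their members, 44 moved beyond it and 1 changed sign after a call; of values of named genes 927 stayed within 1.5-fold, 267 moved and 0 with a call changed sign. Where no cause is named below, the cause was not tested. No filter on low values left both counts at 488 and 1207 by construction, since a gene below an FPKM of 1 cannot pass 2-fold with a pseudocount of 1. Keeping failed estimates at 0 could not move a list median, since failed symbols had been left out of the lists. Using only status OK left each list median unchanged, and the median and upper quartile scalings gave nearly the same values. The 13 alternatives are therefore not 13 separate checks. Depth limits the low side of the large ratios: *Tnmd* rests on 114 aligned bases in the negative library, and its ratio moves with the pseudocount.

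The pseudocount scales the ratio of genes at low levels by construction. With 0.1 the medians were 3.24 for tendon, 2.55 for skeletal muscle, −3.70 for endothelium, −5.26 for erythroid, −4.35 for macrophage, −4.30 for epidermis and −2.29 for glia and nerve. With 5 there were 222 genes higher and 394 lower (36.0% higher), and the medians were 1.14 for tendon, 0.49 for skeletal muscle, −0.71 for endothelium, −2.09 for macrophage, −1.84 for epidermis, −0.64 for glia and nerve and −0.31 for the cell cycle; immediate early genes were at −0.32, percentile 0.83. With a minimum FPKM of 5, which tests fewer genes, 323 were higher and 658 lower (32.9%), with medians of 1.77 for skeletal muscle and −2.65 for endothelium (percentile 2.35), and glia and nerve at percentile 6.62. Without a filter, cartilage (0.034, percentile 99.3), Wnt (0.40, percentile 100) and immediate early genes (−0.49, percentile 0.89) stood apart and osteoblast (−0.29, percentile 7.83) no longer did. At 1.5-fold 919 genes were higher and 2863 lower (24.3%), and at 4-fold 166 and 354 (31.9%), by construction of the threshold.

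Setting the median ratio to 1 or equalising upper quartiles shifts the ratios and moved the split. With the median ratio set to 1 the share was 41.6%, the cell cycle median −0.15 and that of reference genes −0.56; with equal upper quartiles these were 41.7%, −0.15 and −0.55. Rescaled to equal sums (TPM), which makes a pseudocount of 1 weigh less and lets 15090 genes pass the filter in place of 12096, 1593 genes were higher (49.7%). The medians were then 3.15 for tendon, 2.49 for skeletal muscle, −2.86 for endothelium, −1.78 for glia and nerve, 0.15 for FGF, 1.03 for Wnt (percentile 100), −0.027 for the cell cycle and −0.42 for reference genes, with immediate early genes at −0.59, percentile 0.01. Without haemoglobin genes, rescaled, 15117 genes passed the filter and 1468 were higher (46.2%), and the medians were 2.44 for skeletal muscle, −2.94 for endothelium, −3.74 for epidermis, −1.85 for glia and nerve, 0.96 for Wnt (percentile 100), −0.11 for the cell cycle, −0.50 for reference genes and −0.66 for immediate early genes (percentile 0). Without small RNAs, rescaled, 15105 passed and 1732 were higher (53.0%), and the medians were 3.30 for tendon, 0.76 for joint, 2.63 for skeletal muscle, −2.94 for endothelium, −1.72 for glia and nerve, 0.24 for FGF, 1.13 for Wnt (percentile 100), 0.060 for the cell cycle and −0.33 for reference genes, with immediate early genes at −0.55, percentile 0.02. After removal of the length trend the joint median turned from 0.10 to −0.028 (percentile 97.0), and the cell cycle list, at −0.45, stood apart at percentile 1.38.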

Other observations

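All tests in this part, and the lists first described in it, were chosen after the values had been seen. Mast cell and basophil genes were lower in ScxGFP-positive cells: 10 of 10 measured genes by at least 2-fold, with a median log2 ratio of −4.23. *Cpa3*, which encodes a mast cell carboxypeptidase, stood at 1.85 FPKM in positive and 271 in negative cells, and the protease genes *Prss34* and *Tpsb2* at 0.0701 (about 195 aligned bases) against 20.3 and 0.161 against 21.5. Neutrophil genes were lower too, 7 of 7 (median −2.25), with *S100a9* at 0.230 (about 256 aligned bases) against 19.3 and *Mpo* at 0.127 against 19.2. Among genes of axon guidance, which also pattern limb nerves and vessels, 8 of 40 were higher and 5 lower, with a median of 0.44 at percentile 100 of matched random lists. *Epha3* (4.83 against 0.367) and *Sema3a* (9.10 against 2.21) were higher, and *Unc5b* (2.54 against 9.83), *Sema4a* (0.544 against 4.05) and *Robo4* (0.0864 against 3.24), the last also in the endothelial list, were lower.

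Imprinted genes were higher in ScxGFP-positive cells: 14 of 24 measured genes by at least 2-fold and 0 lower, with a median of 1.11 at percentile 100. The highest were *Dlk1*, *Meg3* (65.0 against 8.22 FPKM) and *Rian* (78.0 against 10.95), neighbours on chromosome 12; the 54-base *AF357355*, at 110892851 to 110892904, lies within the span of *Rian* (110842155 to 110899921). Elsewhere *Plagl1* stood at 67.9 against 17.3, *Cdkn1c* at 212 against 62.6, *Igf2* at 398 against 220 and *H19* at 291 against 245.

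The imprinted list was written after its values had been seen, so its percentiles describe the listed genes and are no independent support. With the length trend removed the median of the list was 1.03, against 1.11 before. Without the 5 genes of the chromosome 12 domain the median of the other 19 was 0.86, so the high ratios were not confined to that domain. The list lay at percentile 100 when matched on length and level, and again without the domain. A list written after high values had been seen can lie there in either case, so these percentiles rule out neither explanation. Dilution of mesenchymal transcripts by blood and epidermal cells in the negative library could raise genes of any mesenchymal cell. The limb mesenchyme list, with a median of 0.039, has members on both sides, so it does not decide this, and dilution and a difference among mesenchymal cells cannot be told apart here.

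Skeletal muscle genes were higher in the positive library although the sort was on a tendon reporter. The length trend is argued against, since with random lists matched on length and level the list lay at percentile 100. If muscle cells entered the positive gate, muscle genes outside that list should be higher too, and a median of 2-fold was set as the limit after the values had been seen. Of 42 further muscle genes 15 were measured, with a median log2 ratio of 0.91 (−0.22 to 2.15) at percentile 100, 6 at least 2-fold higher and 0 lower by as much. That is above matched random lists but short of 2-fold, and most of these genes lie near 1 FPKM, where the pseudocount compresses the ratio. The test does not decide, since muscle cells in the gate need not give any set fold. Myogenic cells in the positive gate, and expression of muscle genes in ScxGFP-positive cells of another kind, cannot be told apart here, as these are pools of cells.

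Most blood, epidermal and mast cell genes were low but above 0 in the positive library; *Gata1*, *Ms4a2* and *Mcpt8* were among those listed at 0. If the signal came from a single pool of carried-over RNA, each lineage should keep a like share of its level in the negative library. Among genes at 5 FPKM or more there, the median share was 4.19% for 12 epidermal genes (quartiles 3.05% to 4.68%), 3.92% for 16 macrophage genes (1.85% to 6.19%) and 1.44% for 8 erythroid genes (0.983% to 2.32%). The 2.92-fold span lay just within the limit set for a single pool after the values had been seen. The quartile ranges of epidermal and erythroid genes did not overlap, which a single pool also required, so the test does not decide. A further 8 mast cell genes had a median of 0.717% (0.513% to 1.20%) but were listed after low values had been seen. The length trend spanned 0.48 log2 units, which is small beside the median log2 ratios of these lists. That span was taken over genes at 5 FPKM or more in both libraries, which few of these lineage genes reach. It therefore does not decide whether length has a part in the differences between lineages. A single pool, whole cells carried over at different rates, and low expression in positive cells cannot be told apart here.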
